A study of Bos taurus with 5 samples.

How the data were processed

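The material was total RNA of longissimus dorsi muscle from 5 Jiaxian Red cattle, with 1 library per animal prepared with an RNA library kit, per the labels' protocols. Per the file headers, the deposited values were FPKM, fragments scaled by transcript length and by the mapped fragments of the library, given by the authors for each transcript and library. The submitters' processing notes name the genome build UMD3.1, HTSeq 0.6.0 and DESeq2 1.10.1 without saying what each was used for. The aligner, the program that estimated FPKM per transcript and the annotation release were not given in the sources used here. A doubt remains over the build: of 7423 genes matched by symbol to a RefSeq table of ARS-UCD2.0, 7397 (99.6%) overlapped their position there, so coordinates are printed as the table gives them, with no build claimed.

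The table listed 13391 transcripts of 9022 genes, 7589 with a symbol and 1433 without; 136 transcripts carried assembly names and 241 were 0 in all 5 libraries. Transcript FPKM were summed per gene identifier, because the comparisons planned beforehand concerned genes. The transcript numbers of 2630 of 7571 numbered genes (34.7%) had gaps below the highest listed number, so a gene's sum covers only its listed transcripts. Values were low for some genes that muscle expresses strongly, among them CKM at 16.2 ± 12.3 FPKM (SD, n = 5), so levels of single genes may be incomplete. No counts were given and the values are estimates per transcript, so read depth is unknown and no counting interval or floor was computed. Exact zeros occurred for genes that all cells use and are reported as listed at 0, without a mean.

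Analyses used log2(FPKM + 1), a detection limit of a mean of 1 FPKM, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Fold values are powers of 2 of the mean log2 ratio of FPKM + 1 and understate the difference for low genes. All 5 libraries formed 1 group, numbered as in the labels, and no comparison between groups was possible. Gene pairs were compared within libraries with an exact two-sided sign-flip permutation test, adjusted by the Benjamini-Hochberg method over the 29 of 58 pairs with both members listed. The same log2 ratios were tested with limma 3.58.1 in R 4.3.3, as a moderated one-sample test with adjusted p under 0.05 as the threshold. It takes the spread of each pair partly from all 29 pairs together, most of which share POLB and are not independent. The spread of a gene list was the SD over libraries of the mean deviation of its detected members, ranked among 10000 random lists matched in 20 bins of mean expression. Lists with under 3 detected members were not ranked. Libraries standing apart were found with Dixon's gap ratio, with 0.71 as the limit for 5 libraries and 0.829 for 4.

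Before the data were examined, 27 gene lists, 58 pairs, the tests, the alternatives and the rule for naming genes were chosen; 171 of the 270 list symbols were listed. The rule named POLB, the 10 genes of highest mean, the 10 of greatest SD among detected genes, the 10 of smallest SD at a mean of at least 10 FPKM, and both members of each pair. It also named, in each list, the 3 members of highest mean and the 2 of greatest SD, members under a mean of 1 FPKM, and genes among all these with a distant library. Genes with no symbol were counted and not named. CKM, PDK4, ACSL1, PLIN4, VDAC3 and the gene families and lists added later were named after values had been seen, except that the list of further interferon-response genes was chosen before its values were looked at.

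Values were simulated for 6136 genes at their real mean levels, each varying independently with the median SD of the real genes, 0.25. The gap rule was met by 5.44% of unchanged genes, and 5.5% of unchanged lists reached the 95th percentile. In that simulation 20 of 20 planted lists were recovered, and 98.5% of genes raised by 3 log2 units in library 1. Real genes differ in spread, with a 90th percentile SD of 0.63, and can vary together, so these rates may not hold for them. For limma's test on 1000 simulated ratios, 99% of the 200 planted ratios were recovered and 1% of the others were called.

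The alternatives were a pseudocount of 0.1, a detection limit of 5 FPKM, no limit, 1 FPKM in every library, rescaling to a fixed total per library (TPM), median-ratio size factors, leaving out each library in turn, limma for the pairs, and leaving out mitochondrial genes from the share of the top 10. Genes with no row in the table, such as MYH1, MYH2, BCL2 and MKI67, were not analysed here. No column of the table was left unmapped.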

Results

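RNA sequencing was carried out on longissimus dorsi, the long muscle of the back, from 5 Jiaxian Red cattle aged 18 months. Each animal gave 1 library, and the 5 libraries formed 1 group. The series set out to find genes that bear on muscle growth in this breed, and its title names POLB, which encodes DNA polymerase beta, the gap-filling enzyme of base excision repair. The cultured myocytes of the title were not analysed here, and with 1 group there was no comparison between conditions. The comparisons below set genes against each other within each library and describe the spread between libraries, each from a different animal. The table held 13391 transcripts of 9022 genes, as FPKM, fragments scaled by transcript length and library size, summed here over the listed transcripts of each gene. Read depth was unknown, because no counts were given; the summed FPKM per library ran from 193706 in library 1 to 223251 in library 4.

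The most abundant genes with a symbol were of the contractile apparatus and the mitochondrial genome. COX1 and COX2, the mitochondrially encoded core subunits of cytochrome c oxidase, averaged 13074 ± 2191 and 6019.9 ± 1978 FPKM (SD, n = 5). ACTA1, the skeletal muscle actin, averaged 5134 ± 463 FPKM, the beta-tropomyosin gene TPM2 4203 ± 419, the slow troponin C gene TNNC1 3976 ± 829.5, and the slow myosin heavy chain gene MYH7 3329 ± 276. The other 4 of the 10 most abundant genes had no symbol in the table and all lay on chromosome 2 within the span of TTN, the giant sarcomere protein titin, as placed in the ARS-UCD2.0 gene table. Together these 10 genes held 29.6% ± 1.85 of the summed FPKM (SD, n = 5), and the 12 listed mitochondrial genes held 12.0% ± 1.99, with the highest share, 15.3%, in library 4. Of these 12, COX3, ATP6, ATP8 and ND4 averaged under 1 FPKM, so the mitochondrial share came almost wholly from the other 8 and may be too low. A mean of at least 1 FPKM was reached by 6136 genes (68.0%), of which 5178 were at 1 FPKM or above in every library; 2172 genes averaged at least 10 FPKM, 216 at least 100 and 28 at least 1000. Spearman's rho between libraries, taken across detected genes, ran from 0.890 to 0.923; genes are not independent replicates.

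Fast and slow fibre genes were both abundant, and neither type was higher in every pair. Fast members were higher in 5 of 5 animals for the regulatory myosin light chains, where MYLPF exceeded the slow form MYL2 by 5.60-fold, and for troponin T, where TNNT3 exceeded TNNT1 by 1.30-fold. MYBPC1, named as the slow myosin-binding protein gene, averaged 2631 ± 238 FPKM. It exceeded the fast form MYBPC2, at 351 ± 44.2 FPKM, by 7.50-fold in 5 of 5 animals. MYBPC1 was not in the list of slow sarcomere genes chosen beforehand, and its excess does not measure a share of slow fibres. Troponin I divided the animals: the slow gene TNNI1 was higher than the fast gene TNNI2 in 4, and lower in library 4. The fast light chain gene MYL1 averaged 1065 ± 127 FPKM against 0.724 ± 0.230 for MYL3, of which the table listed a single, high-numbered transcript, so that this pair does not measure the whole slow gene. MYL2 and TNNT1 also had gaps in the numbering of their listed transcripts, while MYLPF, TNNT3, MYL1, MYBPC1, MYBPC2, TNNI1 and TNNI2 had none, so the 3 pairs with the fast member higher set a possibly partial slow sum against one without gaps.

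The slow over fast ratio, on the log2(FPKM + 1) scale, averaged -2.49 ± 0.31 for MYL2 and MYLPF, -0.38 ± 0.22 for TNNT1 and TNNT3, 0.17 ± 0.45 for TNNI1 and TNNI2, 2.91 ± 0.19 for MYBPC1 and MYBPC2, and -9.27 ± 0.18 for MYL3 and MYL1 (SD, n = 5). With 5 animals the exact two-sided sign-flip test cannot give p below 0.063, the value reached by 4 of the 5 pairs (Benjamini-Hochberg 0.0697 over 29 pairs); TNNI1 and TNNI2 gave an exact p of 0.5 (adjusted 0.5). In limma's moderated test the adjusted p was 9.56e-10 for MYL2 and MYLPF and 9.15e-11 for MYBPC1 and MYBPC2, but 0.0824 for TNNT1 and TNNT3. These values rest partly on the spread of the other pairs, most of which contain POLB, so they may be too small or too large for a single pair. Of 12 slow and fast pairs chosen beforehand 5 had both members listed; MYH1 and MYH2, the adult fast myosins, were not analysed here, so no slow myosin share was computed.

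**Figure D1:**
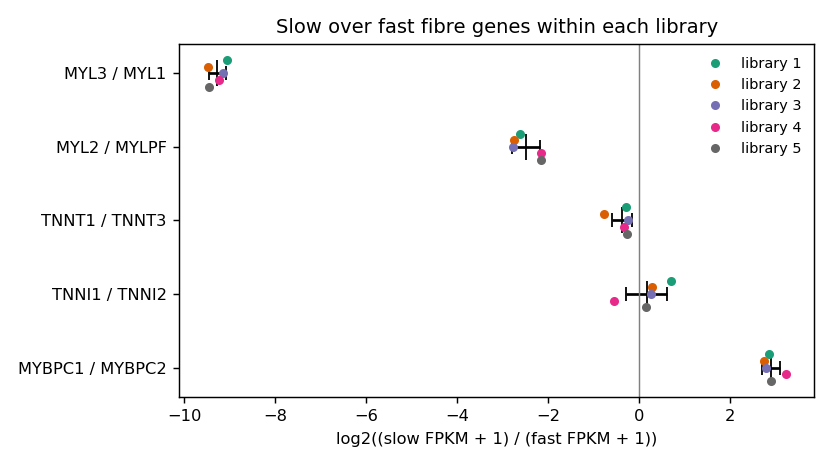
Log2 ratio of slow over fast fibre genes, log2((slow FPKM + 1) / (fast FPKM + 1)), in each of the 5 libraries (points), with the mean and SD (bars). MYBPC1 over MYBPC2 lies at 2.91, MYL2 over MYLPF at -2.49, and TNNI1 over TNNI2 spans 0.

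POLB was expressed in all 5 muscles at a moderate level that differed 2.39-fold between the lowest and the highest animal. Its FPKM was 8.49 in library 1, 14.4 in library 2, 19.6 in library 3, 20.3 in library 4 and 15.1 in library 5, a mean of 15.6 ± 4.74 (SD, n = 5). This placed POLB at rank 1449 of the 6136 detected genes, above 76.4% of them. Its SD on the log2(FPKM + 1) scale, 0.47, was greater than that of 82.0% of detected genes. Library 1 set much of this spread and of the 2.39-fold range, since libraries 2 to 5 lay between 14.4 and 20.3 FPKM. The gene, ENSBTAG00000000225, lay on chromosome 27 from 37192520 to 37217387 in the table's coordinates.

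Both listed POLB transcripts covered this same interval. POLB-201 carried most of the signal, at 12.7 ± 3.18 FPKM (SD, n = 5). POLB-202 was listed at 0 in library 1 and at 2.63, 5.47, 3.14 and 2.97 FPKM in libraries 2 to 5, which was 15.5% to 27.9% of the gene's FPKM in those 4 animals. A value of 0 in an estimate of this kind does not exclude the transcript, since abundant genes such as the ribosomal protein gene RPL3 were also listed at 0 in single libraries.

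**Figure D2:**
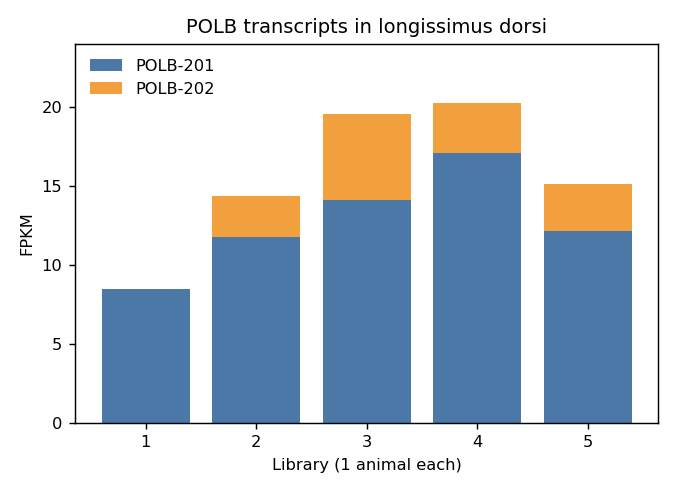
FPKM of the transcripts POLB-201 and POLB-202 in each of the 5 libraries, stacked so that the bar height is the gene's FPKM. The total runs from 8.49 in library 1, where POLB-202 was listed at 0, to 20.3 in library 4.

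Among DNA polymerases, POLB stood well above the listed sums of the replicative enzymes and of most that act at damaged DNA, but below REV3L. It was higher in 5 of 5 animals than 7 of the 9 polymerases listed. These were POLA1, POLE and POLD1, which act in replication, and POLK, POLM, POLQ and REV1, which act at damaged DNA. Only REV1, at 2.73 ± 0.559 FPKM, and POLD1, at 1.40 ± 0.310 FPKM, averaged 1 FPKM or more (SD, n = 5). POLK, POLM, POLQ and REV1 all had gaps in the numbering of their listed transcripts and POLB had none, so their sums may be partial. REV3L, the catalytic subunit of polymerase zeta, averaged 25.0 ± 2.76 FPKM and was higher than POLB in 5 of 5 animals, by 1.62-fold. The mitochondrial polymerase gene POLG, at 12.3 ± 2.37 FPKM, lay below POLB in 4 of 5 animals and above it in library 1; without library 1, POLB was higher than 8 of the 9.

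Within base excision repair, POLB, PARP1 and APEX1 were the abundant members. PARP1, which senses strand breaks, averaged 20.6 ± 2.06 FPKM and was higher than POLB in 5 of 5 animals, by 1.35-fold. APEX1, the main abasic site endonuclease, averaged 13.6 ± 1.79 FPKM and did not separate from POLB, which was higher in 3 animals and lower in libraries 1 and 5. The other 9 listed genes lay below POLB in 5 of 5 animals. They comprised the glycosylases SMUG1 (3.63 ± 1.15 FPKM), OGG1 (1.52 ± 0.233), MUTYH (1.37 ± 0.420), NTHL1 (1.17 ± 0.477) and NEIL1, the end-processing gene APTX (1.43 ± 0.404), and the ligation genes LIG1, LIG3 and XRCC1 (SD, n = 5). NEIL1, LIG1, LIG3 and XRCC1 averaged under 1 FPKM, and XRCC1 was listed at 0 in library 5 and NEIL1 at 0 in library 1.

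For these POLB pairs the mean log2 ratio was -0.70 ± 0.45 against REV3L, 0.28 ± 0.42 against POLG, -0.43 ± 0.32 against PARP1 and 0.13 ± 0.35 against APEX1 (SD, n = 5). The exact sign-flip p was 0.063, the smallest possible, for each pair with 1 direction in 5 of 5 animals, 0.188 for POLG and 0.438 for APEX1; after adjustment over 29 pairs these were 0.0697, 0.201 and 0.453. Limma's adjusted p was 0.0056 for REV3L, 0.0553 for PARP1, 0.223 for POLG and 0.530 for APEX1. Of the 12 polymerase and 18 repair pairs chosen beforehand, 9 and 11 had both members listed. All 20 POLB pairs share POLB, so they are not independent, and 9 of the 16 genes below POLB averaged under 1 FPKM, where the added 1 FPKM sets the size of the ratio. Of the genes below POLB, XRCC1, LIG3, NTHL1, SMUG1, APTX, POLK, POLM, POLQ and REV1 had gaps in the numbering of their listed transcripts. Their sums may therefore leave out transcripts, as may those of POLG and REV3L.

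**Figure D3:**
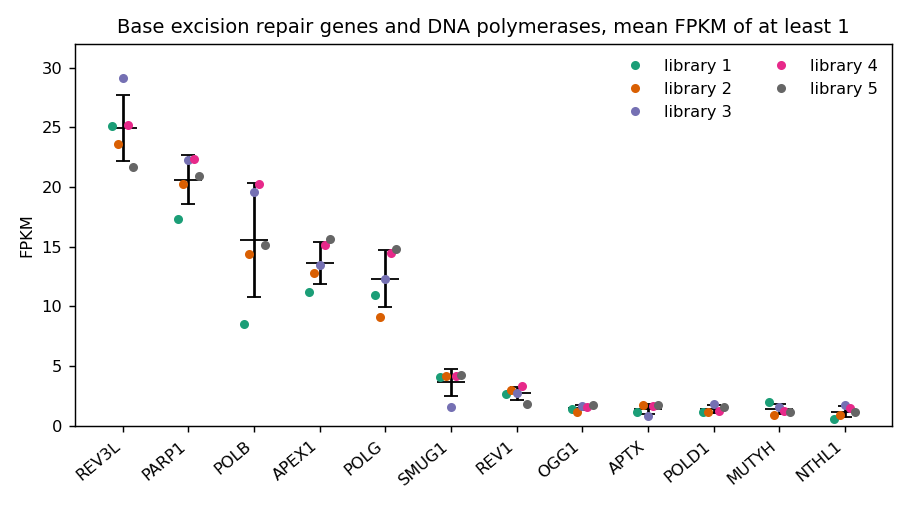
FPKM in each library (points) with mean and SD (bars) for POLB and the listed base excision repair genes and DNA polymerases whose mean reached 1 FPKM. REV3L, PARP1, POLB, APEX1 and POLG lie between 12.3 and 25.0 on average, and SMUG1 and the others lie at 3.63 or below.

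Genes of proliferation were low in these muscles, and 2 cell-cycle inhibitors lay well above them. Of 8 listed proliferation genes 4 averaged 1 FPKM or more: MCM6 at 4.97 ± 1.65, CCNE1 at 2.68 ± 1.32 and MCM2 at 2.55 ± 0.342 FPKM (SD, n = 5), and MCM5. The mitotic genes CDK1, CCNA2, CCNB1 and TOP2A lay under a mean of 1 FPKM. Among the inhibitors, CDKN1A averaged 19.8 ± 11.1 FPKM, from 8.72 in library 1 to 37.8 in library 5, and CDKN1C averaged 16.4 ± 2.38 FPKM. The other detected members of that list lay in the range of the proliferation genes. CDKN2C averaged 3.68 ± 1.69 FPKM, and RB1 was listed at 0 in library 1 and reached at most 1.91 FPKM. Of the apoptosis genes chosen beforehand, 4 of 10 pro-apoptotic and 1 of 6 anti-apoptotic genes were listed, and their listed sums were low. BAD averaged 4.98 ± 0.982 FPKM, CASP8 1.92 ± 0.971 and the anti-apoptotic BCL2L1 4.68 ± 1.16. APAF1 had a mean of 2.92 FPKM, while BAX stayed under 1 FPKM. APAF1, CASP8, BCL2L1 and BAX had gaps in the numbering of their listed transcripts, so their sums may be partial. BAD had no such gap.

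The 4 regulator pairs with both members listed each pointed 1 way in 5 of 5 animals. IGF2 was 6.46-fold above IGF1, and the muscle ubiquitin ligase gene TRIM63 was 3.89-fold above FBXO32, the other ligase of muscle atrophy. ACTA1 was 279-fold above ACTC1, the cardiac and embryonic actin, and CPT1B, the muscle form of carnitine palmitoyltransferase 1, was 6.96-fold above the liver form CPT1A. The log2 ratios were -2.69 ± 0.66 for IGF1 over IGF2, -1.96 ± 0.33 for FBXO32 over TRIM63, 8.12 ± 0.89 for ACTA1 over ACTC1 and 2.80 ± 0.55 for CPT1B over CPT1A (SD, n = 5; exact p = 0.063 for each, the smallest possible, adjusted 0.0697). Limma's adjusted p, which borrows spread from the other pairs here too, was at most 3.11e-08. IGF1, IGF2 and CPT1A had gaps in the numbering of their listed transcripts, so that their sums may leave out transcripts. The other 12 of 16 pairs chosen beforehand were not analysed here.

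Most genes differed little between the libraries. The median SD of log2(FPKM + 1) over the 6136 detected genes was 0.25, and 223 genes (3.63%) had an SD of at least 1. Among genes of at least 10 FPKM the most even was AGFG1, a gene of vesicle transport, at 15.6 ± 0.243 FPKM, followed by UFL1 at 18.2 ± 0.393, DNAJC13 at 10.3 ± 0.231 and MAP3K7 at 11.3 ± 0.268 (SD, n = 5). STK24, ATP6V0A1, MTPAP, DMXL1, GNAQ and PDS5A completed the 10 of smallest spread.

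The 10 genes of greatest spread were each listed at 0.298 FPKM or below in at least 1 library and at 13.2 FPKM or above in another. RPL3 was at 70.6 and 75.4 FPKM in libraries 3 and 4 and at 0.0041, 0.0027 and 0 in libraries 1, 2 and 5. IDH3B, a subunit of a citric acid cycle enzyme, was at 57.5 FPKM in library 3 and 40.5 in library 5 and listed at 0 in the other 3. NDUFS8, a subunit of complex I, was at 32.4 FPKM in library 1, 45.1 in library 4 and 0 in the rest. BOLA was at 36.1 FPKM in library 1 and at most 0.532 elsewhere, and RHOBTB3 at 38.2 FPKM in library 2 and at most 2.25 elsewhere. SMIM20, EPS15, EIF2S1, SUGP2 and NKIRAS1 completed the set. Of the 223 variable genes 88 (39.5%) were under 0.1 FPKM in some library and at 5 FPKM or more in another, and 55 genes had an SD of at least 1 when a value of at least 1 FPKM was required in every library.

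The 5 libraries differed in 3 gene groups whose members moved together: interferon-response genes, fibroblast and matrix genes, and nuclear genes of the respiratory chain. With 1 library per animal, a difference between animals cannot be told apart from one of dissection, RNA quality or library preparation. All 8 listed interferon-response genes lay below their own mean in library 2 and above it in library 3. The antiviral gene OAS1Y was at 4.26 FPKM in library 2 and 19.9 in library 3, MX1 at 0.511 and 7.88, and RSAD2 at 3.40 and 10.9. The 6 matrix genes all lay above their mean in library 4 and below it in library 2, and 5 of 6 lay above it in library 1 and below it in library 5; COL3A1, a fibrillar collagen, was at 625 FPKM in library 1, 609 in library 4, 297 in library 2 and 345 in library 5. All 13 respiratory chain genes lay below their mean in library 1 and above it in libraries 3 and 4, and 12 of 13 lay below it in library 2. COX7A1, a muscle subunit of cytochrome c oxidase, was at 261 FPKM in library 1 and 485 in library 4, and COX6A2, also a muscle subunit and by far the most variable member, at 18.6 and 423.

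The mean deviation of the interferon genes was -0.79 in library 2 and 0.55 in library 3, that of the matrix genes 0.51 in library 1, 0.30 in library 4 and -0.46 in library 2, and that of the respiratory chain genes -0.44 in library 1 and 0.37 in library 4 (log2 scale). For the respiratory chain genes COX6A2 set much of this: their median deviation was -0.21 in library 1, -0.20 in library 2, 0.24 in library 3 and 0.25 in library 4. Their spread over the 5 libraries lay at the 99.98th, 99.84th and 99.35th percentile of 10000 random lists matched on size and expression, and all 3 lists stayed at or above the 95th in 13 of 13 alternative settings applied to every list. With single members left out in turn, a check added after seeing the data, the interferon and matrix lists stayed at or above the 99.8th and 98.4th, but the respiratory chain list stood at the 90.6th without COX6A2. Of the 20 lists with at least 3 detected members 5 reached the 95th percentile, where chance gives 1. The other 2 were pericyte and smooth muscle genes (97.39th), led by MYH11 at 7.82 FPKM in library 1 and at most 0.821 elsewhere, and developmental muscle genes (95.07th), with ACTC1 at 39.3 FPKM in library 1 and 7.58 in library 2. Both rested on library 1: without it they stood at the 77.0th and 57.3rd percentile. They also rested on single members: the smooth muscle list stood at the 82.8th without MYH11 and the 94.7th without ACTA2, and the developmental list at the 82.5th without ACTC1, the 85.4th without MYH3 and the 94.9th without MYH8. The developmental list stood below the 95th without library 2 (92.6th) or library 5 (89.1st) as well. Over the alternative settings that ranked them, the developmental list reached the 95th in 4 of 12 and the smooth muscle list in 8 of 10. With a pseudocount of 0.1 they stood at the 88.4th and 73.9th.

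**Figure D4:**
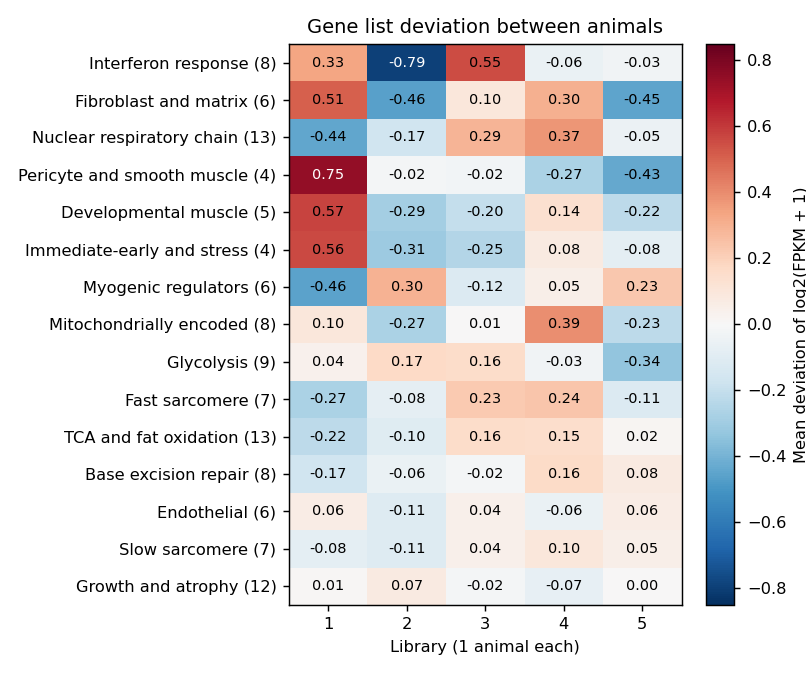
Mean deviation of log2(FPKM + 1) from each gene's own mean over the 5 libraries, for 15 of the gene lists chosen beforehand, with the number of detected members in brackets. Interferon-response genes reach -0.79 in library 2 and 0.55 in library 3, and nuclear respiratory chain genes run from -0.44 in library 1 to 0.37 in library 4, of which COX6A2 sets a large part.

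The remaining 15 lists stood below the 95th percentile. The mean of the slow sarcomere genes (9.12th percentile) varied little, and stayed at or below the 20.3rd under all alternative settings. Its members went both ways, however, with 3 of 7 higher in library 4 than in library 1. MYL2 was at 319 FPKM in library 1 and 756 in library 4, and TNNI1 at 875 and 569. The spreads of the growth and atrophy genes (8.62nd) and the endothelial genes (25.6th) were low as well but depended on the setting, from the 1.92nd to the 55.9th and from the 10.6th to the 60.6th. The endothelial genes CDH5, EGFL7 and EMCN averaged 27.9 ± 3.09, 25.5 ± 2.51 and 18.6 ± 2.16 FPKM (SD, n = 5). Fast sarcomere genes stood at the 76.1st percentile, glycolysis at the 81.5th, the citric acid cycle and fat oxidation at the 70.6th, and mitochondrially encoded genes at the 91.4th. Base excision repair stood at the 42.3rd, DNA polymerases at the 60.7th, proliferation at the 82.2nd, cell-cycle inhibitors at the 85.2nd, pro-apoptotic genes at the 81.7th and nerve and Schwann cell genes at the 50.2nd. The immediate-early and stress list (94.3rd) and the myogenic regulators (94.1st) came close to the 95th. Under the alternatives the immediate-early list reached it in 4 of 13 settings and the myogenic regulators in 3 of 12, while without library 1 they stood at the 62.3rd and 77.45th. The mitochondrially encoded genes reached it in 2 of 13, at the 98.8th without library 1 but the 76.8th without library 4, and glycolysis in 1 of 13. EGR1, an immediate-early gene, was at 28.1 FPKM in library 1 and at most 11.3 in the others, and SIX4 was at 10.3 FPKM in library 1 and 18.3 in library 5. Lists of adipocyte, macrophage, lymphocyte, erythrocyte, satellite cell and anti-apoptotic genes had under 3 detected members; of these the fat synthesis gene SCD averaged 47.6 ± 11.6 FPKM and the macrophage gene MRC1 8.69 ± 3.45. The sex-linked genes chosen beforehand were not analysed here.

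Library 1 stood apart from the others in more genes than any other library. Dixon's gap rule, which chance meets in 5% of genes over the 5 libraries if values are normally distributed, was met by 452 of 6136 genes (7.37%). Library 1 was the distant one for 149 of them, library 4 for 107, library 2 for 82, library 3 for 63 and library 5 for 51. In 98 of the 149 library 1 was the lowest and in 51 the highest. With at least 1 FPKM required in every library, 317 of 5178 genes met the rule. Library 1 also had the most genes under 0.1 FPKM that reached 5 FPKM in another library, 43 of 90. How many of the 98 are such genes was not counted.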

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

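The tests of transcript assignment, sequencing depth, fibre share and leukocytes were chosen after the results they measure had been seen; those on short genes and on further interferon-response genes were not. The gap rule for a library far from the other 4 was applied to 163 reported results and met by 12. Chance gives 8.15 for normally distributed values, so single cases carry little weight.

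In library 1, MYH11, a smooth muscle myosin, was high at 7.82 FPKM, CDKN1C was high at 20.6 FPKM, EYA1, a cofactor of myogenic transcription factors, was listed at 0, and the log2 ratio of POLB over MUTYH was low at 1.66. In library 2, the replication gene MCM5 was listed at 0 and the log2 ratio of TNNT1 over TNNT3 was low at -0.77. In library 3, the slow tropomyosin gene TPM3 was high at 2390.4 FPKM, SMUG1 was low at 1.58 FPKM, and the log2 ratio of POLB over POLM was high at 4.29. In library 4, COX1 was high at 16972 FPKM and COX2 at 9527 FPKM. In library 5, DNAJC13 was low at 9.88 FPKM.

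EYA1 belongs to a wider pattern: 90 detected genes were under 0.1 FPKM in some library and at 5 FPKM or more in another, among them RPL3, IDH3B and NDUFS8. Too little sequencing alone would lose low genes far more often than abundant ones. Of the library values of the 955 genes with a mean of 1 to 2 FPKM, 3.96% lay under 0.1 FPKM, so most were not lost. The rate among abundant genes was not computed beside it, so the part of sequencing depth is not decided. Assignment of reads to other transcripts of the same gene is a candidate explanation: 52 of 1760 genes with gaps in their listed transcript numbers (2.95%) showed the pattern, against 2 of 1286 genes with several transcripts and no gap (0.156%), an odds ratio of 19.5 (Fisher's exact test, p = 1.43e-10). The 2 classes were matched neither on expression nor on the number of listed transcripts, which was 1 for the gapped genes RPL3 and IDH3B. A sum over several transcripts lies under 0.1 FPKM only if each of them does. This lowers the rate in the class without gaps whatever the cause, so the odds ratio does not decide for this explanation. Of genes with a single transcript and no gap, 26 of 2355 also showed the pattern, so that gaps may explain only part of it. The difference between these and the gapped genes was not tested. No biological explanation was tested, since the design has 1 group.

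Nuclear genes of the respiratory chain were lower in library 1 than in library 4 in 13 of 13 genes. So were 24 of 24 NDUF genes, a wider set for complex I chosen afterwards, by 0.78 ± 0.05 on the log2 scale (SE). That set left out NDUFS8, at 32.4 and 45.1 FPKM in these libraries and listed at 0 in the others. A lower share of muscle fibres in library 1 as the whole cause would lower the sarcomere genes about as much. The 14 sarcomere genes differed by 0.34 ± 0.15 (SE), less than complex I by 0.44 ± 0.15. That gap depends on the slow genes (0.18 ± 0.23, 3 of 7 higher in library 4), since the fast ones alone differed by 0.51 ± 0.17. The SE are taken over genes, and libraries 1 and 4 are 1 animal each, so for complex I the question is not decided. For the 13 genes a lower fibre share cannot be told apart either: they exceeded the sarcomere genes by 0.47 ± 0.34. Without COX6A2 they differed by 0.51 ± 0.05, as much as the fast sarcomere genes alone. Endothelial genes (-0.12 ± 0.03), collagens (-0.25 ± 0.10) and smooth muscle genes (-1.02 ± 0.52) were lower in library 4. Under TPM these values were -0.32, -0.48 and -1.55, with the sarcomere genes at 0.18 and complex I at 0.59. A bias against short transcripts cannot be told apart: genes outside these families with a locus under 3000 bases differed from the rest by 0.067 (95% bootstrap interval -0.025 to 0.137), yet the median difference was 0.15 at 3000 to 10000 bases, 0.13 up to 30000, -0.05 up to 100000 and -0.17 above, and locus length is only a proxy for transcript length. No biological explanation was tested, and no measure of RNA quality was at hand.

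Interferon-response genes were low in library 2 and high in library 3, in 8 of 8 genes, by a mean of 1.35 ± 0.25 on the log2 scale (SE). Independent variation of single genes is argued against by 16 further detected interferon-response genes, chosen before their values were looked at: 15 were higher in library 3, by a mean of 0.64 ± 0.11 (SE), and their spread lay at the 99.4th percentile of matched random lists. HERC6, for example, was at 2.26 FPKM in library 2 and 7.12 in library 3. The 10 detected leukocyte markers differed by -0.083 ± 0.110 (SE over genes) between the same libraries, with 4 higher in library 3. They were led by CD74, at 135 FPKM in library 2 and 137 in library 3. As the whole cause, more cells of the kinds these genes mark are argued against. The list does not measure a number of cells, however. The lymphocyte genes CD3D and CD3E averaged under 1 FPKM, so that a change in other leukocytes cannot be excluded. A different exposure of the animals to infection or vaccination may underlie the pattern, but the labels hold no such record and this was not tested.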

How the results depend on the processing

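Alternatives that restrict the analysis to genes of at least 0.1 FPKM in every library or to genes with no numbering gap, POLB-201 alone (12.7 FPKM) and leaving out single list members were added after seeing the data; the others were planned. The number of variable genes, 223, depended on the processing. It was 525 with a pseudocount of 0.1, 813 after rescaling to TPM, where 7817 genes were detected, 108 at a mean of at least 5 FPKM, 55 with at least 1 FPKM in every library, 108 with at least 0.1 FPKM in every library and 120 without genes with numbering gaps. The pseudocount gives low genes more weight, TPM does so and tests more genes, and the rest test fewer. With a mean of at least 5 FPKM, 3570 genes were detected, 254 genes had a distant library and 3 lists reached the 95th percentile; with no limit 773 genes had a distant library, and without gapped genes 3 lists reached the 95th percentile. Without COX6A2 4 lists did, the respiratory chain no longer among them. Rescaling to TPM put POLB at 74.5 and moved no share of the top 10, which was 26.3% without mitochondrial genes.

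Leaving out each library in turn gave 6081 to 6160 detected genes, 14.4 to 17.3 FPKM for POLB, 209 to 243 variable genes, 4 to 6 lists, 387 to 411 genes with a distant library, 29.1% to 30.1% for the top 10, 3 fast-over-slow pairs, 7 to 8 polymerases and 9 repair genes below POLB, and 4 regulator pairs. In limma's test 2 fast-over-slow pairs, 7 polymerases, 9 repair genes and 4 regulator pairs passed. No pair changed its mean direction; 16 of 174 pair values moved by more than 1 SD, all with the pseudocount of 0.1 and all to larger ratios. The slow myosin share and its alternatives were not run, because MYH1 and MYH2 were not analysed here. No paired analysis was possible because there was 1 group. Read depth was unknown, so no limit from it could be given.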

Other observations

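The families below and the tests of clock and fuel-use genes were chosen after values had been seen. Several gene families beyond the report's lists also differed between the libraries. Some share members with those lists, such as the NDUF genes with the respiratory chain list. Among 43 cytosolic ribosomal protein genes, 40 lay above their own mean in library 4 and 3 in library 1, with mean deviations of 0.41 and -0.38 on the log2 scale. Mitochondrial ribosome genes, 37 in all, deviated by 0.26 in library 4 and -0.32 in library 1, and 14 ATP synthase genes by 0.38 and -0.26. Their spreads lay at the 100th, 100th and 98.0th percentile of matched random lists, and that of 24 NDUF genes at the 99.93rd. RPL3 and NDUFS8, both listed at 0 in some library, were left out of their families. The counts and percentiles therefore do not cover every detected member. The deviations of these families in libraries 1 and 4 kept their sign under TPM and median-ratio scaling. For 23 proteasome genes (96.6th percentile), the deviation of -0.27 in library 1 kept its sign, and that of 0.10 in library 4 changed sign under TPM.

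Collagens differed from these families in library 1, where 15 of 16 lay above their own mean, with a mean deviation of 0.38; in library 4 they too lay above it, in 11 of 16 genes and by 0.12, or 0.02 under TPM. Their list stood at the 99.0th percentile. Leukocyte markers (98.7th) lay above their mean in 8 of 10 genes in library 1 and in 9 of 10 in library 4, and below it in 9 of 10 in libraries 2 and 3. MRC1, a macrophage receptor, was at 11.1 FPKM in library 1, and at 6.19 and 3.99 in libraries 2 and 3. Of the 10 markers, MRC1, AIF1 and PTPRC also belong to the macrophage or lymphocyte lists, and CD74, CTSS and CD44 can be expressed by other cells of the tissue, so the list does not measure a number of cells.

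Outside those lists, VDAC3, a mitochondrial membrane channel, was at 13.7 FPKM in library 1 and 194 in library 3. CKM, the muscle creatine kinase, was at 35.5 FPKM in library 1 and at most 18.5 elsewhere. The mitochondrial genes COX3, ATP6, ATP8 and ND4 were listed at means of 0.0623, 0.0591, 0.179 and 0.158 FPKM, while COX2 and ND3, transcribed from the same strand, averaged 6019.9 and 1049 FPKM.

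Hypotheses of different sampling times and of different feeding states could not be decided. The arms of the clock run opposite to each other, so the mean over 6 detected clock genes (35.7th percentile of matched random lists) cannot show a shift in time. The difference between ARNTL, CLOCK and NPAS2 on one side and PER2, CRY1 and CIART on the other had a spread at the 56.3rd percentile, on too few genes to exclude one. For feeding, PDK4, which limits glucose oxidation during fasting, was at 56.1 FPKM in library 1 and 347 in library 3, and ACSL1 and PLIN4 also differed. The 5 other detected fuel-use genes stood at the 18.4th percentile, but their members went both ways: between the same libraries ETFDH was at 31.4 and 45.2 FPKM, and PLIN2 at 12.1 and 8.64. With PDK4, ACSL1 and PLIN4, which had prompted the question, the list stood at the 98.4th percentile, a value that those 3 genes set.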
